A study of Escherichia coli with 10 samples.

How the data were processed

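RNA was sequenced from 10 cultures of Escherichia coli MG1655, a laboratory K-12 strain, grown in M9 minimal medium with glucose. Per the labels' protocols, 2 colonies were picked, grown overnight and diluted into fresh medium, and the cultures were treated for 5 h. The 5 groups of 2 biological replicates each were no treatment, and CdTe-2.4 or CdSe-2.4 quantum dots at 10 nM, each in light and in dark. Quantum dots are semiconductor nanocrystals, here of cadmium telluride or cadmium selenide. The labels do not say whether the untreated cultures were illuminated, so an effect of light alone was not separated from an effect of the dots. Per the labels, libraries followed the protocol of Shishkin et al., and single reads of 50 nt were sequenced with strand information on 3 lanes.

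The submitters' processing notes name Trimmomatic 0.32, Bowtie2 2.2.3, SAMtools 0.1.18, HTSeq 0.6.1 and DESeq 3.4, with no role, order or settings. The genome build and the strand setting of the read counting are not given in the sources used here. The deposited table holds 1 row per gene for 4271 genes. Its values are a signal that the authors had already scaled: within each library 100% of the non-zero values were whole multiples of 1 step, within a tolerance of 0.02 read, so each value is a read count divided by a size factor of the library. These size factors lay between 0.752 and 1.43. The whole reads were recovered from the steps. They came to between 528193 and 1031262 reads assigned to genes per library, out of 19.7 to 40.1 M reads in the table (M, megareads). Rows that name no gene stayed out of all tests. Reads with no feature took 83.6% to 85.1% of a library, reads of low alignment quality 7.56% to 8.89%, unaligned reads 4.41% to 5.64%, ambiguous reads 0.0106% to 0.0145%, and reads assigned to genes 2.24% to 3.06%. The p-values measure the spread between cultures of 1 strain, and the counting precision is set by the assigned reads, not by the whole depth.

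The test chosen at first was edgeR's quasi-likelihood test on counts. Because the deposited values were normalised and not counts, limma 3.58.1 in R 4.3.3 was used instead, with a mean-variance trend on log2(value + 1). Fold changes are on that scale, which understates the change of genes with few reads. Genes with a mean of at least 10 normalised reads were kept, which left 3217 genes. All 10 libraries entered 1 fit with 1 mean per group, which gave 5 residual and a median of 8.8 prior degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, separately in each of 9 comparisons. The 9 were each treated group against no treatment, light against dark for each dot, CdTe against CdSe in each lighting, and the difference between the light effects of the dots. On data simulated for CdTe light against no treatment, over 3222 genes, the fit recovered 68 of 99 genes changed 2-fold (68.7%) and 94 of 97 genes changed 4-fold (96.9%), with 10 false calls and 2 calls in a comparison simulated with no change. The simulated spread followed the trend with read level alone and was the same in all libraries, so recovery in the real libraries may be lower.

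The 39 gene lists were fixed before the data were examined. The 38 with at least 4 tested genes were tested with limma's camera on the same log2 values, with a preset inter-gene correlation of 0.01, in place of the voom values planned for counts. Camera with an estimated correlation and fry were alternatives. The genes named were 31 stress and metal markers and, per comparison against no treatment or of light against dark, up to 10 rises and 10 falls of largest log2 fold change among called genes with a mean of at least 10 CPM and groups that did not overlap. In the other comparisons the limit was 5 each, and in the difference between light effects overlap was not considered. Up to 4 called members of a described list were also open to be named. Other genes were chosen after their values were seen, and the text says so. Gene symbols were matched to the RefSeq gene table of assembly ASM584v2, 4070 by symbol and 191 by synonym, with 10 unmatched. That table was used only for names and for which genes lie next to each other, and no coordinates are given because the build of the deposited table is not named.

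Alternatives chosen before the data were examined were edgeR 4.0.16 with RLE size factors and DESeq2 1.42.0, both on the recovered reads, no filter, the replicate number as a block, only the libraries of the groups compared, stable RNA genes left out, and each library left out in turn. In the last, the lone library of a group is assumed to vary like the other groups. The test chosen at first, edgeR with TMM, became an alternative, and its use on the recovered reads was decided after seeing the data. Alternatives added after seeing the data were edgeR with TMM and the replicate block, pseudocounts of 0.5 and 5, values scaled to equal gene totals, and lists of the genes that flank list members. Scaling to equal totals or by TMM moved the median log2 fold change of all genes by less than 0.1 in each comparison. Comparisons that share the untreated libraries were set beside 100 simulated data sets with no change. Python 3.11.15, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for the summaries and plots.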

Results

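Transcript reads were measured in 10 libraries of Escherichia coli MG1655, 2 each from cultures with no treatment, with CdTe dots in light, with CdTe dots in dark, with CdSe dots in light and with CdSe dots in dark. The series addresses which responses belong to superoxide, a reactive oxygen species, and which to stress from cadmium-containing dots. Between 528193 and 1031262 reads per library were assigned to genes, which is 2.24% to 3.06% of the reads in the table. Replicates of a group correlated across genes with r of 0.96 to 0.979 on the log2 scale, where genes are not independent replicates. Chi-square per degree of freedom between replicates was 2.86 to 7.12, so no replicates were copies of 1 library. The CdTe light cultures differed most by this measure, and the CdTe dark cultures least.

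The assigned reads did not follow the known abundance of transcripts in this species. The 22 ribosomal RNA genes held 40 recovered reads over the 10 libraries together. The gene of the transfer-messenger RNA ssrA had a mean of 4.38 normalised reads, that of the RNase P RNA rnpB 5.48, that of elongation factor Tu tufA 0.86 and that of the glycolytic enzyme gapA 11.7. Ribosomal RNA and tufA have near-identical gene copies, whose reads can be set aside for low alignment quality, so they bear less on this point. The 54 ribosomal protein genes took 0.167% of the assigned reads, and their median lay at percentile 25.2 of protein-coding genes in reads per base. The gene with most reads was psrO, between pnp and rpsO, with a mean of 21350 normalised reads. Next came tqsA, beside pntB, with 11024 normalised reads. These genes were chosen after their values were seen. Only 10.7% of the chromosome lies outside annotated genes in ASM584v2. Yet 96.5% to 97.4% of the reads neither unaligned nor of low quality lay in no feature. These shares argue against counting on the gene's own strand or on both strands. Because the strand setting is not given, each value below is given as reads assigned to a gene and is not stated to be that gene's own transcript. For some of the called genes a gene next to them on the chromosome is named, and which neighbours to name was chosen after the values were seen.

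**Figure D1:**
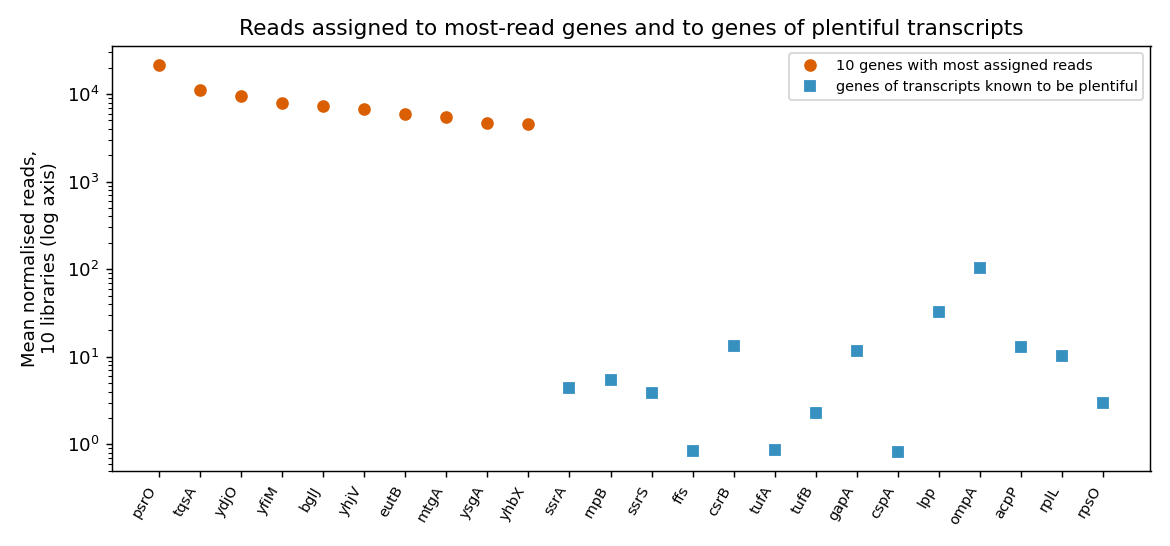
Mean normalised reads over 10 libraries (log axis) of the 10 genes with most assigned reads (circles) and of 14 genes whose transcripts are known to be plentiful in this species (squares). The circles lie between 4535 and 21350 normalised reads, and the squares between 0.82 for cspA and 103.3 for ompA.

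Across the 9 comparisons 67 genes were called in at least 1. Reads assigned to tusA were higher in all 4 treated groups, and tusA was the 1 gene called in all 4 comparisons with no treatment. Of the 31 listed markers of oxidative, metal, envelope and DNA stress, 26 were tested by limma. The other listed markers did not enter that test, so it does not show whether their reads changed. None of the 26 was called by limma in any comparison, and edgeR and DESeq2 on the recovered reads also called 0. At an unadjusted p under 0.05, between 0 and 3 of the 26 passed per comparison, and 0 passed when adjusted over the list of markers alone. The superoxide response regulator soxS had 53.6 ± 3.2 normalised reads without treatment (SD, n = 2) and 45.2 ± 13.7 in CdTe light, 50.8 ± 5.0 in CdTe dark, 39.3 ± 2.1 in CdSe light and 62.7 ± 8.4 in CdSe dark (SD, n = 2 each). The cadmium and zinc exporter zntA had 849.0 ± 356.1 without treatment (SD, n = 2) and 478.6 ± 220.9 in CdTe light, 636.1 ± 39.7 in CdTe dark, 665.8 ± 22.7 in CdSe light and 943.2 ± 42.1 in CdSe dark (SD, n = 2 each). By limma's camera 0 of 38 gene lists passed the threshold in each of the 9 comparisons, with 1 to 4 lists per comparison at an unadjusted p under 0.05 and 0 with an estimated correlation. By fry 1 list passed in 1 comparison, given below, and fry's test of change in either direction passed 6 lists in CdSe dark against no treatment. The share of reads in no feature, given above, argues against counting on the gene's own strand. These results therefore cannot show whether the own transcripts of the markers and list members changed.

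**Figure D2:**
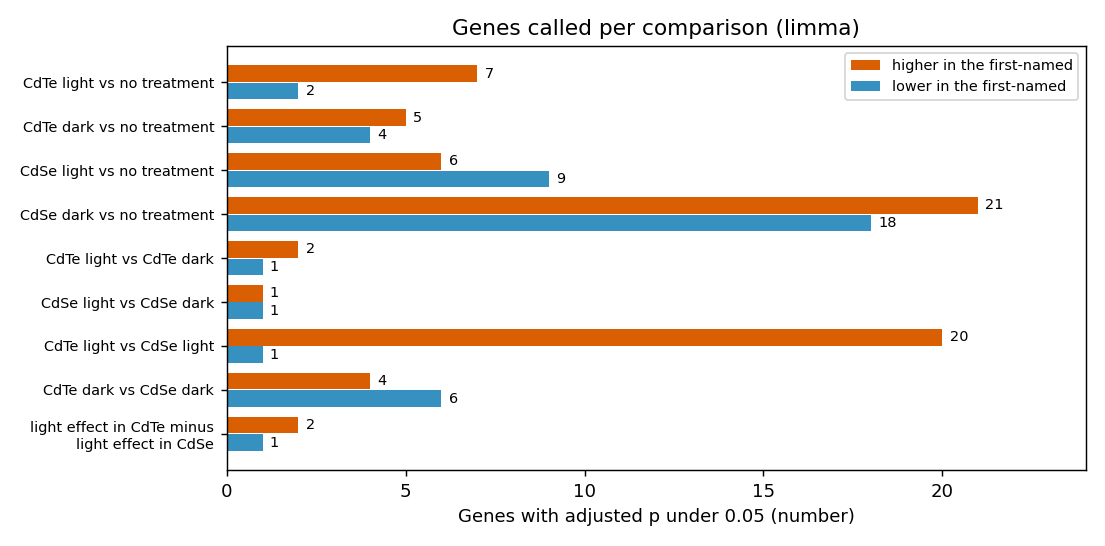
Number of genes with an adjusted p under 0.05 (limma, 3217 genes tested) in each of 9 comparisons, split by direction. CdSe dark against no treatment had 21 higher and 18 lower genes, and CdTe light against CdSe light had 20 higher and 1 lower, or 20 and 18 without CdTe light replicate 1.

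The comparison of CdTe light with no treatment asked how cells responded to illuminated CdTe dots. Reads rose at tusA (b3470), a sulfur carrier gene that lies beside zntA, from 261.4 ± 59.1 to 3093 ± 159.5 normalised reads (SD, n = 2 each). This was a log2 fold change of 3.58 with a standard error of 0.16 and an adjusted p of 1.14e-08. At yjcC (b4061), which lies beside soxS, reads rose from 367.0 ± 3.8 to 3162 ± 1476 (SD, n = 2 each), a log2 fold change of 3.02 with a standard error of 0.27 and an adjusted p of 2.39e-05. At yjaH (b4001), between hupA and zraP, the gene of a zinc-binding periplasmic protein, reads rose from 221.5 ± 19.8 to 1748 ± 707.4 (SD, n = 2 each), a log2 fold change of 2.92 with an adjusted p of 1.88e-05. The 4 other rises were yigM beside metR (log2 2.50), hupA (2.04), ykgL beside ykgO (1.37) and yhbX beside the arginine synthesis gene argG (1.18). The 2 falls were yeiG beside the iron-siderophore receptor gene cirA (log2 -1.51) and yciU beside oppF (-0.84). At yeiG the untreated cultures differed, with 1183.7 and 2576.3 normalised reads, which limits each comparison of it with no treatment. In all, 7 genes rose and 2 fell, and 286 genes had an unadjusted p under 0.05. None of the 484 tested members of the fixed lists was called over all genes, and 4 of 38 lists held a member that passed when adjusted over the list alone. These members were zntA (log2 -0.84) and zitB (0.45) of the zinc and cadmium export list, yggX of the SoxRS list (1.27), zupT of the Zur list (-0.56) and cho of the SOS list (-1.14). The zinc and cadmium export list held only 4 tested genes. At zntA the groups overlapped, with 1100.8 and 597.2 normalised reads without treatment and 634.8 and 322.4 in CdTe light. The 9 calls depended on single libraries, except tusA, yjcC and yjaH, which were called in each of 4 fits that left out 1 library: the count was 15 without no treatment replicate 1, 8 without no treatment replicate 2, 33 (18 higher, 15 lower) without CdTe light replicate 1 and 5 without CdTe light replicate 2, of which 7, 6, 7 and 4 were among the 9. DESeq2 called 28 genes (18 higher, 10 lower), 9 of them shared, and the fit on the compared groups alone called 5.

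**Figure D3:**
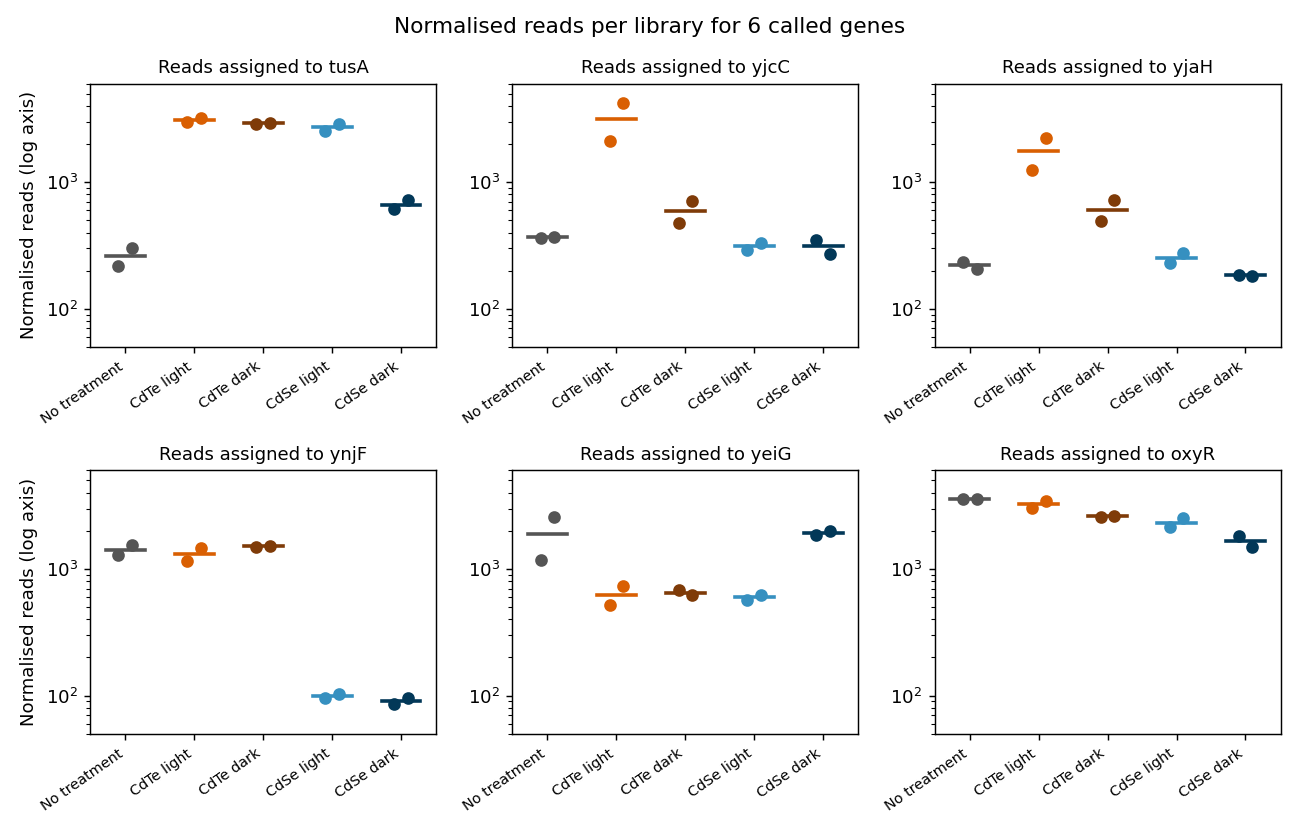
Normalised reads (log axis) assigned to 6 called genes in each of 10 libraries; points are libraries and bars are group means of 2. Both CdSe groups lie at 85.5 to 103.1 normalised reads for ynjF, below the 1146 to 1549 of the 6 other libraries.

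In CdTe dark against no treatment, reads at tusA again rose, to 2916 ± 30.5 normalised reads (SD, n = 2), a log2 fold change of 3.49 with a standard error of 0.16 and an adjusted p of 1.57e-08. Reads at yjaH rose to 606.8 ± 164.6 (SD, n = 2), a log2 fold change of 1.43 with an adjusted p of 0.0242. The other rises were tesB beside the ammonium transporter gene amtB (log2 1.54), ykgL (1.41) and rimO beside bssR (1.01). Falls were found for yeiG (log2 -1.42), clcB (-1.32) and elyC (-0.83). The transfer RNA gene leuP was also called lower, at 0.0 and 0.9 normalised reads against 21 and 130.3. It is uncertain, because near-identical leucine tRNA copies can share its reads and the untreated cultures differed. In all, 5 genes rose and 4 fell by limma, 320 genes had an unadjusted p under 0.05, and 0 of the 484 list members were called, with 8 of 38 lists holding a member that passed when adjusted over the list alone. The count of 9 was 23 without no treatment replicate 1, 1 without no treatment replicate 2, 1 without CdTe dark replicate 1 and 2 without CdTe dark replicate 2, and tusA was called in each of these 4 fits. DESeq2 called 23 genes (13 higher, 10 lower), edgeR with RLE size factors 15, and the fit on the compared groups alone 1.

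In CdSe light against no treatment, reads at tusA rose to 2712 ± 227.9 normalised reads (SD, n = 2), a log2 fold change of 3.39 with a standard error of 0.16 and an adjusted p of 1.19e-08. Reads at ynjF (b1758), between ynjE and nudG, fell from 1422 ± 180.5 to 99.6 ± 5.0 (SD, n = 2 each), a log2 fold change of -3.82 with an adjusted p of 4.02e-09. The other rises were ykgL (log2 1.64), tesB (1.34), ycgJ beside pliG (1.16), panM between the branched-chain amino acid transport genes livK and livJ (1.15) and rimO (0.91). Falls included thrA (log2 -1.82), yeiG (-1.55), lgoT beside the chemoreceptor gene tsr (-1.48), yraP (-1.30), rne (-1.06) and gcvB (-1.02), and leuP, uncertain as above, at 1.2 and 4.0 normalised reads. Of the 21 tested genes of the peroxide response (OxyR) list, 0 rose and 1 fell, the glutathione reductase gene gor, with a log2 fold change of -1.01 and an adjusted p of 0.0318; 2 members passed when adjusted over the list alone, and 4 of 38 lists held such a member. In all, 6 genes rose and 9 fell. The count of 15 was 31 without no treatment replicate 1, 2 without no treatment replicate 2, 2 without CdSe light replicate 1 and 3 without CdSe light replicate 2, with tusA and ynjF called in each of the 4 fits and gor in 0 of them. DESeq2 called 29 genes (10 higher, 19 lower).

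In CdSe dark against no treatment, reads at tusA rose to 665.5 ± 77.3 normalised reads (SD, n = 2), a log2 fold change of 1.36 with a standard error of 0.16 and an adjusted p of 0.00134. Reads at ynjF fell to 90.1 ± 6.6 (SD, n = 2), a log2 fold change of -3.96 with an adjusted p of 2.45e-09. Reads at oxyR, which lies beside oxyS and sthA, fell from 3594 ± 5.1 to 1654 ± 244.1 (SD, n = 2 each), a log2 fold change of -1.13 with an adjusted p of 0.00198. Larger rises than that of tusA were those of yigM (log2 2.03), yhhI (1.70), appY (1.63), tesB (1.55) and ybdM (1.51). Rises also included afuC (log2 1.34), ygbA (1.23), tqsA (1.22) and panM (1.12). Falls included purN (log2 -1.63), yraP (-1.30), yejB (-1.08), ybaZ (-0.97), eco (-0.97), rne (-0.97) and yaiW (-0.97). Of the fixed lists, the SoxRS list had 0 of 23 tested genes higher and 1 lower, ribA (log2 -0.93, adjusted p = 0.00694). The OxyR list had 0 of 21 higher and 1 lower, oxyR itself, and the phosphate starvation list 0 of 9 higher and 1 lower, ugpQ (log2 -0.76, adjusted p = 0.0109). Adjusted over the list alone, 2, 1 and 1 members passed, and 13 of 38 lists held such a member. In all, 21 genes rose and 18 fell. The count of 39 was 25 without no treatment replicate 1, 15 without no treatment replicate 2, 5 without CdSe dark replicate 1 and 17 without CdSe dark replicate 2; tusA, ynjF and oxyR were called in each of these 4 fits, ribA in 3 and ugpQ in 1. DESeq2 called 59 genes (34 higher, 25 lower).

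The comparisons with no treatment share their untreated libraries, so some overlap arises without any effect. CdTe light and CdTe dark shared 3 rises and 1 fall, where independent lists would share 0.011 and 0.002 and simulated unchanged groups shared 0.01 and 0. CdSe light and CdSe dark shared 4 rises and 4 falls, where independent lists would share 0.039 and 0.05 and simulated unchanged groups shared 0.01 and 0.02. The 4 other pairs shared 3 to 6 calls. Correlations of fold changes over genes were 0.484 to 0.62 between the 6 pairs of comparisons, and 0.499 to 0.504 in simulated unchanged groups. The covariance exceeded the simulated one by 0.0268 to 0.0481. The untreated group holds 2 libraries and could not be split so that each part keeps 2, so part of the shared calls may come from the shared controls. Simulated groups with no change have few calls to share, so their shared counts near 0 do not measure that part. The simulation also gave all groups the same spread per gene. Replicates differed by a median of 0.3 on the log2 scale in no treatment and 0.194 to 0.291 in the treated groups, so the simulated covariance may be too low.

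For CdTe dots, light against dark gave higher reads at yjcC, with 3162 ± 1476 against 589.3 ± 163.7 normalised reads (SD, n = 2 each), a log2 fold change of 2.37 with a standard error of 0.27 and an adjusted p of 0.00141. Reads at yjaH were also higher in light (log2 1.49, adjusted p = 0.0396), and reads at yfiB beside rplS were lower (log2 -0.81, adjusted p = 0.0396). In all, 2 genes rose and 1 fell by limma, with 322 at an unadjusted p under 0.05, and 0 of the 484 list members were called, with 4 of 38 lists holding a member that passed when adjusted over the list alone. The count of 3 was 48 (15 higher, 33 lower) without CdTe light replicate 1, 1 without CdTe light replicate 2, 0 without CdTe dark replicate 1 and 1 without CdTe dark replicate 2. The call of yjcC was lost without CdTe dark replicate 1 (log2 2.08, adjusted p = 0.0616) and in the fit on the compared groups alone, which called 0 genes. DESeq2 called 16 genes (8 higher, 8 lower), the 3 among them.

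For CdSe dots, reads at tusA were higher in light than in dark, with 2712 ± 227.9 against 665.5 ± 77.3 normalised reads (SD, n = 2 each), a log2 fold change of 2.03 with a standard error of 0.16 and an adjusted p of 1.97e-05. Reads at yeiG were lower in light, with 597.3 ± 40 against 1912 ± 93.4 (SD, n = 2 each), a log2 fold change of -1.68 with an adjusted p of 0.0352. These were the 2 genes called, with 201 at an unadjusted p under 0.05, and 0 of the 484 list members were called by limma, with 4 of 38 lists holding a member that passed when adjusted over the list alone. The tusA call was kept in each of 4 fits that left out 1 library, and the yeiG call in 0 of them, with log2 fold changes of -1.75 to -1.61 and adjusted p up to 0.573. The count was 1 without CdSe light replicate 1, CdSe light replicate 2 or CdSe dark replicate 2, and 2 without CdSe dark replicate 1. DESeq2 called 10 genes (3 higher, 7 lower), and the fit on the compared groups alone 13 (4 higher, 9 lower).

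The dots differ in their chalcogen, tellurium or selenium, and were compared at the same dose and time. In light, reads were higher with CdTe than with CdSe at ynjF (log2 3.69, adjusted p = 6.3e-09), yjcC (3.26, adjusted p = 1.36e-05), yjaH (2.73, adjusted p = 2.85e-05), yigM (2.13) and yjgL beside the arginine synthesis gene argI (2.10). Reads at yihY were lower with CdTe (log2 -1.60). Other called genes, chosen after their values were seen, were rlmC beside the arginine transport gene artJ (log2 1.56), recD beside argA (1.74) and yhbX beside argG (1.37). In all, 20 genes were higher and 1 lower, and 0 of the 484 list members were called by limma, with 290 genes at an unadjusted p under 0.05. Adjusted over the list alone, 5 of 38 lists held a member that passed, among them gor (log2 0.73) and oxyR (0.48) of the OxyR list. By fry the Zur list of zinc uptake genes was lower with CdTe (adjusted p = 0.0196), while camera gave it an adjusted p of 0.445, and 0.962 with an estimated correlation. The count of 21 was 38 (20 higher, 18 lower) without CdTe light replicate 1, 9 without CdTe light replicate 2, 5 without CdSe light replicate 1 and 13 without CdSe light replicate 2; ynjF, yjcC, yjaH and rlmC were called in each of these 4 fits. The fit on the compared groups alone called 11 genes.

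In dark, reads were higher with CdTe than with CdSe at ynjF (log2 4.05, adjusted p = 1.79e-09), tusA (2.13, adjusted p = 5.11e-06), yjaH (1.69, adjusted p = 0.00802) and the chemoreceptor gene trg (0.73). Reads were lower with CdTe at yeiG (log2 -1.55), norW beside hypF (-1.15) and ascB beside hycI (-0.91), and at leuP and leuV, which are uncertain as near-identical tRNA copies. In all, 4 genes were higher and 6 lower, and 0 of the 484 list members were called by limma, with 196 genes at an unadjusted p under 0.05. Adjusted over the list alone, 7 of 38 lists held a member that passed, among them entS of the Fur list (log2 -0.74) and oxyR of the OxyR list (0.66). The count of 10 was 3 without CdTe dark replicate 1, 2 without CdTe dark replicate 2, 3 without CdSe dark replicate 1 and 2 without CdSe dark replicate 2; ynjF and tusA were called in each of these 4 fits. DESeq2 called 21 genes (14 higher, 7 lower), the fit on the compared groups alone 45 (26 higher, 19 lower), and the fit without stable RNA genes 5, with 4 higher and 1 lower, where norW and ascB were no longer called (adjusted p = 0.0575).

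The light effect itself differed between the dots at 3 genes. The light effect in CdTe minus that in CdSe was -1.94 on the log2 scale at tusA (standard error 0.23, adjusted p = 0.00234), where the CdSe cultures differed between light and dark and the CdTe cultures were high in both. At yjcC the difference was 2.36 (standard error 0.38, adjusted p = 0.0358), where the CdTe cultures had more reads in light. At leuP it was 6.19, uncertain as above, and edgeR with TMM or RLE factors did not call it, which left 1 positive and 1 negative difference. None of the 484 list members was called by limma, with 203 genes at an unadjusted p under 0.05, and 3 of 38 lists held a member that passed when adjusted over the list alone. The tusA call was kept in each of 8 fits that left out 1 library and the yjcC call in 3 of them, with log2 differences of 1.86 to 2.85 at yjcC. The count of 3 was 14 without CdTe light replicate 1, 3 without CdTe light replicate 2, 2 without CdTe dark replicate 2 or CdSe dark replicate 1, and 1 without CdTe dark replicate 1, CdSe light replicate 1, CdSe light replicate 2 or CdSe dark replicate 2. DESeq2 called 11 genes (8 positive, 3 negative differences) and the fit on the libraries of the dots alone 8.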

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

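The tests of explanations in this part were chosen after the results were seen. A difference between groups was found by the test of the light effect in CdTe minus that in CdSe, which called 3 genes: tusA (log2 -1.94), yjcC (2.36) and leuP (6.19). Among reads not assigned to genes, both CdSe light libraries had more unaligned reads than both untreated libraries, with a mean of 5.32% against 4.69%. Ambiguous reads were above both untreated libraries (mean 0.0114%) in CdTe light (0.0136%), CdTe dark (0.0138%) and CdSe dark (0.0136%). An exact permutation test over all 945 ways to part the 10 libraries into 5 pairs gave an adjusted p of 0.316 for unaligned and 0.16 for ambiguous reads, over 5 shares tested.

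Transcripts that are plentiful in this species had few assigned reads. Removal of ribosomal RNA as the whole cause is argued against, since only 12 of 54 ribosomal protein genes lay above the median of protein-coding genes in reads per base. A candidate explanation is that reads were assigned on the strand opposite to each gene, since the libraries keep strand. Of the reads neither unaligned nor of low quality, 96.5% to 97.4% lay in no feature, where that explanation needs most reads to be. Only 10.7% of the chromosome lies outside annotated genes in ASM584v2. Counting on both strands, or on the gene's own strand, would leave most reads in genes, so these shares argue against both settings. The reads and the strand of each gene were not used here, so counting with the other strand setting was not tried, and no biological explanation was tested.

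Genes next to members of known regulons carried part of the changes, among them tusA beside zntA and yjcC beside soxS. Dependence on 1 library is argued against for tusA, yjcC and yjaH in CdTe light, where the lowest log2 fold change in any fit that left out 1 library was 2.49. A candidate explanation is that transcripts of the neighbouring gene run over the called gene on the other strand. Of 427 tested genes that flank members of the fixed lists, 22 (5.15%) were called in at least 1 comparison, against 4 of 484 members (0.83%; Fisher's exact test, two-sided, p = 8.1e-05). The flanking genes had more reads (median 71.8 against 43.3 normalised reads), and when matched on reads in 20 bins 15.3 calls were expected among them instead of 22 (permutation test, one-sided, p = 0.0026, 100000 permutations), so read level accounts for part of the difference. Of 2306 other tested genes 41 (1.78%) were called, so most of the 67 called genes were neither members nor flanking. Fisher's exact test gave p = 0.000129 for flanking against other genes and p = 0.164 for members against other genes. These shares restate the pattern and do not decide between the neighbour's transcript and a response of the called genes themselves, since the strand of each gene was not used here.

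Reads at ynjF were lower in the 4 CdSe libraries, in light and in dark. The lower of the median log2 fold changes of all genes against no treatment was 0.001 in the CdSe groups. The deposited size factors can by themselves hold this median near 0, so it does not test a scaling error. Scaling to equal gene totals, which does not fix the median, gave medians of 0 in CdSe light and -0.027 in CdSe dark. A fall like that of ynjF was not shared by the median gene under either scaling. Loss of a stretch of chromosome with ynjF and its neighbours is argued against by ynjE and nudG, whose lowest log2 difference between CdSe and CdTe in the same lighting was -0.43. A change within ynjF in the CdSe cultures, a transcript on either strand and a response to CdSe dots stay open.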

How the results depend on the processing

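The replicate block in edgeR, pseudocounts of 0.5 and 5, and equal gene totals were chosen after the data were seen. The edgeR test with TMM was the one chosen at first, and its use on recovered reads was decided after the data were seen. In the order CdTe light, CdTe dark, CdSe light and CdSe dark against no treatment, light against dark in CdTe and in CdSe, CdTe against CdSe in light and in dark, and the difference of light effects, the calls numbered 9, 9, 15, 39, 3, 2, 21, 10 and 3. DESeq2 called 28, 23, 29, 59, 16, 10, 25, 21 and 11. The replicate block gave 38, 32, 40, 84, 18, 11, 29, 20 and 10, and in edgeR 37, 34, 45, 66, 18 and 16 for the first 6, and 29 and 13 for the last 2. In the same order, the block gave 23, 15, 15, 44, 9, 4, 23, 12 and 9 genes higher and 15, 17, 25, 40, 9, 7, 6, 8 and 1 lower, against 7, 5, 6, 21, 2, 1, 20, 4 and 2 higher and 2, 4, 9, 18, 1, 1, 1, 6 and 1 lower without it. Replicate numbers were not taken to pair the cultures, since the labels tie no number to a colony and 3 of 10 pairs of groups had deviations of same-numbered libraries correlated above 0.1. These were no treatment with CdTe light (0.23), no treatment with CdSe light (0.2) and CdTe light with CdSe light (0.253), a hint of shared structure in those groups, and the lowest was -0.04. Of the 10 correlations, 8 were above 0. The fit on the compared groups alone gave 5 for CdTe light, 1 for CdTe dark, 0 for light against dark in CdTe, 13 in CdSe, 11 and 45 for CdTe against CdSe, and 8 for the difference of light effects. RLE factors gave 15 for CdTe dark, and leaving out stable RNA genes 5 for CdTe against CdSe in dark. Leaving out 1 library gave ranges of 5 to 33, 1 to 23, 2 to 31, 5 to 25, 0 to 48, 1 to 2, 5 to 38, 2 to 3 and 1 to 14. The lists past the threshold stayed at 0 with an estimated correlation and with the block, were 1 by fry for CdTe against CdSe in light, and ranged from 0 to 1 with 1 library left out. Calls shared by CdSe light and CdSe dark fell from 8 to 5 among genes changed at least 2-fold. The cause was not tested. Fewer libraries leave fewer degrees of freedom, but this alone does not account for fits with more calls. On the compared groups alone, 45 genes against 10 were called for CdTe against CdSe in dark. Over 111 called gene results, none changed direction. Calls were kept in 177 of 456 values with 1 library left out, in 71 of 111 on the compared groups alone, in 104 with edgeR and TMM, in 106 with RLE, in 102 with no filter, and in 101 of 102 with DESeq2, which gave no adjusted p for 9 others. The block lost none of the 111. The assigned reads, 2.24% to 3.06% of each library, limit the precision for genes with few reads.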

Other observations

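The lists of flanking genes were formed after the data were seen, so these tests are not independent of the calls described above. Of 36 such lists, between 0 and 4 passed per comparison with the preset correlation, and 0 passed in any comparison with an estimated one. By limma's camera with the preset correlation, genes that flank the arginine synthesis list were higher in CdTe light than in no treatment (12 genes, adjusted p = 0.00625), than in CdTe dark (adjusted p = 0.0389) and than in CdSe light (adjusted p = 2.7e-05). With an estimated correlation the adjusted p was 0.499, 0.809 and 0.689. They were lower in CdSe light than in CdSe dark (adjusted p = 0.00834, and 0.588 with an estimated correlation). Genes that flank the Zur list of zinc uptake genes were higher than in no treatment in CdTe light (8 genes, adjusted p = 0.0191), CdTe dark (adjusted p = 0.013) and CdSe light (adjusted p = 0.00022), and the adjusted p was 0.499, 0.762 and 0.321 with an estimated correlation. They did not pass in CdSe dark (adjusted p = 0.597), and were higher in CdSe light than in CdSe dark (adjusted p = 0.00152, and 0.501 with an estimated correlation). Genes that flank the zinc and cadmium export list, tusA among them, were higher in CdTe light than in no treatment (8 genes, adjusted p = 0.0133) and in CdSe light than in CdSe dark (adjusted p = 0.0273), with an adjusted p of 0.499 and 0.501 with an estimated correlation. Genes that flank the Fur list of iron uptake genes were lower in CdSe light than in no treatment (22 genes, adjusted p = 0.00022) and than in CdSe dark (adjusted p = 0.000849), with an adjusted p of 0.4 and 0.588 with an estimated correlation. The light effect differed between the dots for the flanks of the arginine (adjusted p = 0.000127), Fur (adjusted p = 0.00491) and Zur lists (adjusted p = 0.00803), with an adjusted p of 0.499, 0.762 and 0.499 with an estimated correlation.

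The first principal component of the log2 values took 21.4% of the variance. On it, replicate 1 and replicate 2 lay at -6.1 and 15.3 in no treatment, at -2.3 and 16.8 in CdTe light and at -10.7 and 3.25 in CdSe light. They lay at -8.09 and -6.27 in CdTe dark and at -0.61 and -1.31 in CdSe dark.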
